A study of Homo sapiens with 6 samples.

How the data were processed

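Bulk RNA sequencing gave 6 libraries of human dermal lymphatic endothelial cells, 3 from cells given PBS and 3 from cells given IFNγ, with RNA purified on columns per the labels' protocols. The groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates were separate cell preparations, so p-values measure the spread between these samples alone, which may be technical. The authors deposited 1 table of raw counts, whole numbers per gene symbol, with 19930 genes and a column for each library. The genome build was hg19 per the submitters' processing notes; the aligner, the counting rule, its use of strand and the annotation are not given in the sources used here. No coordinates were used. The total counts ranged from 54639974 to 80583994 per library, and 3335 genes had 0 counts in all 6 libraries.

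The counts were analysed in R 4.3.3 with edgeR 4.0.16. The default filterByExpr filter on the groups left 13366 genes and removed 6564. Libraries were scaled by TMM, with factors of 1.03 to 1.04 in PBS and 0.962 to 0.9695 in IFNγ libraries, and the groups were compared by the two-sided quasi-likelihood F test without covariates. p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The standard error of a log2 fold change was the Wald error at the fitted means, from the negative binomial variance times the gene's quasi-dispersion, or the counting error where that was larger. It pools the spread of both groups and across genes, so a fold change is less certain than its error where the SD in a group is a large part of the mean. Levels are TMM-scaled CPM, as mean ± SD of 3 libraries. The floor for a gene with no counts was 3 counts per library, and the interval of a ratio with 1 to 3 counts in a group is an exact binomial interval at 95%. Reads carried no molecular identifiers in any source used here, so such floors and intervals cover counting error only.

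Before the data were examined, 43 gene lists with 1042 entries, the rule for named genes, the tests and the alternatives were fixed. 2 entries were matched through synonyms in a RefSeq gene table of assembly GRCh38.p14, and 7 entries matched no row. The lists covered IFNγ signalling, GTPases, type I interferon genes, both MHC classes, the immunoproteasome, checkpoint ligands, chemokines, adhesion, NF-κB targets, cell death, endothelial identity and structure, the cell cycle, metabolism, stress, other skin cells, ribosomal proteins and RNA quality. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over all lists with at least 5 tested members, and again with an estimated correlation and with fry, whose directional p tests whether a list's genes move one way on balance.

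The rule named the 6 largest rises and 6 largest falls among genes past the threshold with non-overlapping groups and a mean of at least 10 CPM; 16 genes fixed by name; and for each list up to 3 members past the threshold with the largest absolute change at a mean of at least 1 CPM, or else the member with the smallest p. Some genes under the rule are not given in the text. Genes linked to the sex chromosomes by which a donor's sex could be read were never named.

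The test was checked on simulated counts for 13366 genes, of which the filter kept 13185. Both groups were drawn from the real PBS means, the library totals and the dispersions, with 50 genes changed at each of 4 sizes. Genes near 0 CPM with PBS were thus simulated as low in both groups, also where the real IFNγ values were high. The test recovered 58% of genes changed 1.2-fold, 90% of those changed 1.5-fold, 94% of those changed 2-fold and 94% of those changed 4-fold. It called 12 of 13166 unchanged genes, with genes removed by the filter counted as not recovered or not called. Camera found a set of changed genes and called 0 of 40 random sets. The simulated genes varied independently, and far fewer of them changed than the 71.2% in the real data. The check therefore does not show how camera behaves on lists whose genes vary together.

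The alternatives were DESeq2's size factors, library totals alone, no filter beyond 1 count, a filter of 10 CPM in 3 libraries, a replicate block, each library left out, DESeq2 1.42.0, limma-voom, a tested fold of 1.5 with glmTreat, and an adjusted p of 0.01. Medians of gene sets in the closing section have 95% bootstrap intervals from 10000 resamples of genes.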

Results

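Transcript abundance was measured by bulk RNA sequencing in cultured human dermal lymphatic endothelial cells, the cells that line the lymphatic vessels of the skin. The cells were plated at 60000 per well in 6-well plates. From the next day they received phosphate-buffered saline (PBS) as the control or interferon gamma (IFNγ) at 0.5 µg/ml, renewed daily, for a total time not given in the sources used here. Each group held 3 libraries. The deposited counts summed to 80583994, 70658477 and 54639974 in the PBS libraries and to 63527100, 62430411 and 62531169 in the IFNγ libraries, so that 3 counts in a library stood for 0.0372 to 0.0549 CPM, the usual count scaled to library size. Across the tested genes, which are not independent replicates, log2 CPM of libraries of the same group correlated at r = 0.9968 or higher. The principal component that separated the groups held 94.6% of the variance. Pairs of replicate libraries differed by a chi-square of 3.95 to 10.01 per gene, which is more than counting noise alone gives. The spread between replicates beyond counting noise was small, with a common coefficient of variation of 3.33%. Neither value shows whether the replicates were separate cell preparations, so the p-values may measure technical spread. Each library was counted as a replicate.

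The comparison of the groups asked which transcripts of lymphatic endothelium changed under IFNγ, a cytokine that activated T cells and natural killer cells release. The series concerns metabolic change in lymphatic vessels under this cytokine. HLA-DRB1, a chain of an MHC class II molecule that presents peptides to helper T cells, rose from 0.0716 ± 0.0167 to 451.9 ± 9.37 CPM (mean ± SD, n = 3). CXCL9, a chemokine that attracts activated T cells, rose from 0.760 ± 0.350 to 3743 ± 132 CPM, and IDO1, the enzyme that starts tryptophan breakdown, rose from 0.975 ± 0.331 to 4777 ± 62.6 CPM. PROX1, the transcription factor that sets lymphatic identity, fell from 186 ± 9.0 to 62.7 ± 2.77 CPM, and LYVE1, the lymphatic hyaluronan receptor, fell from 105 ± 7.42 to 18.3 ± 0.470 CPM.

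Of 13366 genes tested with edgeR's quasi-likelihood test, 9523 (71.2%) changed at an adjusted p under 0.05, of which 4822 were higher and 4701 lower with IFNγ. Over 2-fold were 994 higher and 1000 lower genes, and over 4-fold 356 higher and 342 lower genes. Scaling by library totals alone gave 3667 higher and 6263 lower genes, or 36.9% higher against 50.6%, because the log2 fold changes of all genes then shifted by a median of -0.10. All changes below are relative to the TMM scaling. Fold changes are given on the log2 scale as IFNγ over PBS, with their standard errors, for 3 libraries in each group. These errors pool the spread across genes, and the PBS values of genes near 0 CPM, such as CXCL9, IDO1 and CIITA, spread more widely than they allow for. Of the 131 tested genes that the naming rule picked, 130 passed the test, and MITF had the highest edgeR adjusted p among these, at 0.024. All 3 IFNγ values lay on the same side of all 3 PBS values in 9893 of the tested genes (74%), where chance gives 10%. Of the named genes past the threshold, the values of MITF alone overlapped. Members named as exceptions within a list, and other members outside that rule, were chosen after their values were seen.

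**Figure D1:**
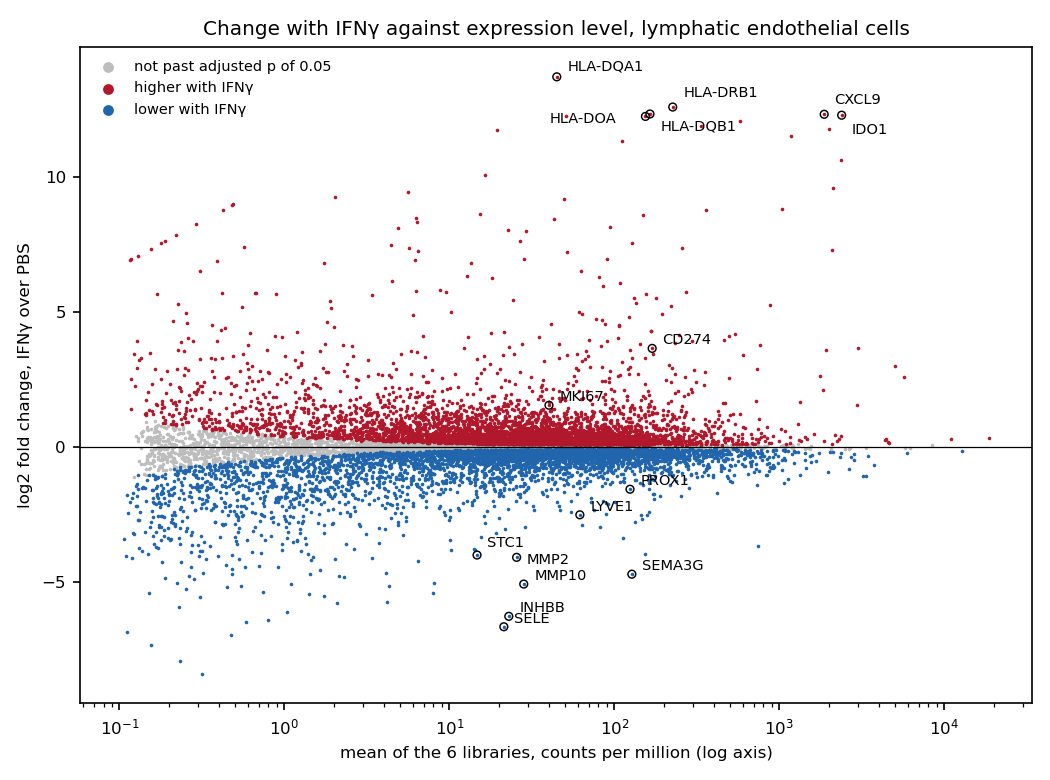
Log2 fold change of each tested gene (IFNγ over PBS, fitted by edgeR) against its mean CPM over the 6 libraries on a log axis; red and blue points passed an adjusted p of 0.05 and grey points did not. The circled genes are the 6 with the largest rises and the 6 with the largest falls at 10 CPM or more, from IDO1 and CXCL9 at the upper right to SELE and INHBB at the bottom, with CD274, MKI67, PROX1 and LYVE1.

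The largest rises at 10 CPM or more were those of HLA-DQA1, HLA-DRB1, HLA-DQB1, CXCL9, IDO1 and HLA-DOA. HLA-DQA1 had 1 count over the PBS libraries together, in replicate 1, and 89.6 ± 1.80 CPM with IFNγ. Its ratio of pooled counts was 19100, with an exact binomial 95% interval of 3430 to 754000 that covers counting error only. HLA-DRB1 rose by 12.61 ± 0.37, HLA-DQB1 by 12.35 ± 0.40, CXCL9 by 12.34 ± 0.16, IDO1 by 12.31 ± 0.13 and HLA-DOA by 12.26 ± 0.40. The largest falls were led by SELE, the endothelial selectin that slows leukocytes on the vessel wall, which went from 42.4 ± 0.125 to 0.412 ± 0.0479 CPM (-6.68 ± 0.17, edgeR adjusted p = 4.48e-25). INHBB, a subunit of activin B, fell from 45.3 ± 3.39 to 0.577 ± 0.00552 CPM (-6.29 ± 0.15). MMP10 and MMP2, which cut matrix proteins, changed by -5.09 ± 0.099 and -4.10 ± 0.078. SEMA3G, a secreted semaphorin, changed by -4.73 ± 0.055 and STC1, a secreted glycoprotein, by -4.01 ± 0.11.

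In the list of IFNγ signalling and transcription factors, 15 of 18 members rose and 2 fell (camera adjusted p = 1.96e-06, and adjusted p = 0.101 with an estimated correlation). IRF1, a transcription factor of the interferon response, rose by 4.13 ± 0.036. CIITA, the master activator of MHC class II genes, rose from 0.191 ± 0.156 to 674 ± 13.5 CPM (11.91 ± 0.29, or 12.66 without PBS replicate 3), and ETV7 rose by 6.96 ± 0.15. SOCS1, which inhibits signalling through Janus kinases, rose by 6.92 ± 0.36 to 12.2 ± 1.14 CPM. The members that fell were the receptor chains IFNGR1 (-0.35 ± 0.036) and IFNGR2 (-0.52 ± 0.036), and JAK1 did not pass the test (-0.046 ± 0.033).

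All 10 tested guanylate-binding proteins and other IFNγ-induced GTPases rose (camera adjusted p = 7.06e-07, and adjusted p = 0.302 with an estimated correlation). GBP5 rose from 1.17 ± 0.431 to 3994 ± 33.0 CPM, GBP4 by 8.82 ± 0.062 and IFI44L by 9.21 ± 0.25. All 32 tested antiviral genes of the type I interferon list rose too (camera adjusted p = 1.93e-15, and adjusted p = 0.137 with an estimated correlation). The largest of these rises at 1 CPM or more were BST2 (8.61 ± 0.11), IFITM1 (8.44 ± 0.22) and XAF1 (8.05 ± 0.24).

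All 14 tested MHC class II presentation genes rose (camera adjusted p = 3.13e-10, and adjusted p = 0.137 with an estimated correlation). In the MHC class I list, 13 of 16 rose (camera adjusted p = 3.64e-06, and adjusted p = 0.13 with an estimated correlation). HLA-B, a classical class I heavy chain, rose from 440.5 ± 10.02 to 5555 ± 156 CPM, and HLA-F rose by 5.32 ± 0.068. TAP1, a subunit of the transporter that brings peptides into the endoplasmic reticulum, rose by 4.18 ± 0.038. The chaperones CALR (-0.79) and CANX (-0.10) fell, of which 1 did so without PBS replicate 2 or without IFNγ replicate 1, and PDIA3 did not pass the test (0.013). All 13 tested genes of the immunoproteasome list rose (camera adjusted p = 6.58e-06, and adjusted p = 0.291 with an estimated correlation). The catalytic subunits that define the immunoproteasome rose most, with 4.49 ± 0.044 for PSMB9, 2.91 ± 0.045 for PSMB10 and 2.71 ± 0.034 for PSMB8.

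T-cell checkpoint ligands and costimulators moved both ways, with 10 of 16 higher and 6 lower (camera adjusted p = 0.108). CD274, which encodes PD-L1, rose from 25.0 ± 0.670 to 314 ± 10.2 CPM (3.65 ± 0.038, edgeR adjusted p = 9.06e-26). PDCD1LG2, which encodes PD-L2, rose by 3.98 ± 0.043, and TNFSF13B, the B-cell survival factor BAFF, by 8.0 ± 0.21. Among the 6 lower members, TNFSF4 changed by -1.96 ± 0.069 and TNFSF18 by -1.04 ± 0.046. Among the apoptosis and pyroptosis effectors, 19 of 28 rose and 7 fell (camera adjusted p = 0.000522, and adjusted p = 0.257 with an estimated correlation). The members with the largest changes were APOL1 (5.67 ± 0.052) and APOL6 (4.16 ± 0.037), apolipoprotein L genes, and CASP1, the inflammasome protease (3.60 ± 0.039).

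Of 21 chemokine genes, 10 rose and 10 fell (camera adjusted p = 0.832). The ligands of CXCR3 on activated T cells rose most, with CXCL10 going from 0.817 ± 0.197 to 2356 ± 78.4 CPM and CXCL11 from 3.01 ± 0.232 to 4738 ± 247 CPM. Among the 10 that fell, CXCL8 went from 233 ± 6.35 to 33.8 ± 2.71 CPM and CCL2 from 459 ± 16.5 to 240 ± 3.27 CPM. CCL20 changed by -5.42 ± 0.20. Leukocyte adhesion and transmigration genes were lower in 10 of 16 cases and higher in 5 (camera adjusted p = 0.237). Beside SELE, VCAM1, a ligand of leukocyte integrins, fell by 2.08 ± 0.13 to 2.30 ± 0.728 CPM, and SELP, a selectin, changed by -1.35 ± 0.16. The 5 higher members included the more abundant ICAM1, which rose from 268 ± 6.38 to 371.3 ± 32.35 CPM. ICAM2 rose from 250.2 ± 10.21 to 361.3 ± 8.44 CPM. Of 17 NF-κB target genes, 12 fell and 4 rose (camera adjusted p = 0.0749). LTB, a lymphotoxin subunit, changed by -3.82 ± 0.087, whereas TNFAIP2 rose by 1.43 ± 0.035 and IL6 by 1.39 ± 0.20.

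The lymphatic endothelial identity list did not pass as a list (camera adjusted p = 0.205): 10 of 19 members fell, 5 rose and 4 did not pass. PROX1 changed by -1.57 ± 0.040 (edgeR adjusted p = 7.83e-19), LYVE1 by -2.52 ± 0.049 (edgeR adjusted p = 3.75e-21) and PDPN, the membrane glycoprotein podoplanin, by -0.32 ± 0.032. FLT4, the receptor of the lymphatic growth factor VEGFC, was at 317 ± 8.70 CPM with PBS and 324 ± 8.16 CPM with IFNγ (0.030 ± 0.034, edgeR adjusted p = 0.447), and its change was -0.073 with library totals alone, also not past the threshold. PKHD1L1 rose by 1.02 ± 0.070. CCL21, the lymphatic chemokine that guides dendritic cells, had 22 counts over the PBS and 18 over the IFNγ libraries and was left out by the filter. Lymphatic valve and collecting-vessel genes divided into 8 higher and 8 lower of 18 (camera adjusted p = 0.745). Their median was 0.029 and became -0.073 with library totals alone, and their mean (-0.40) and camera's direction were downward. In that list KLF4, a factor induced by flow, rose by 3.09 ± 0.092 and the connexin gene GJA4 changed by -3.02 ± 0.14.

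**Figure D2:**
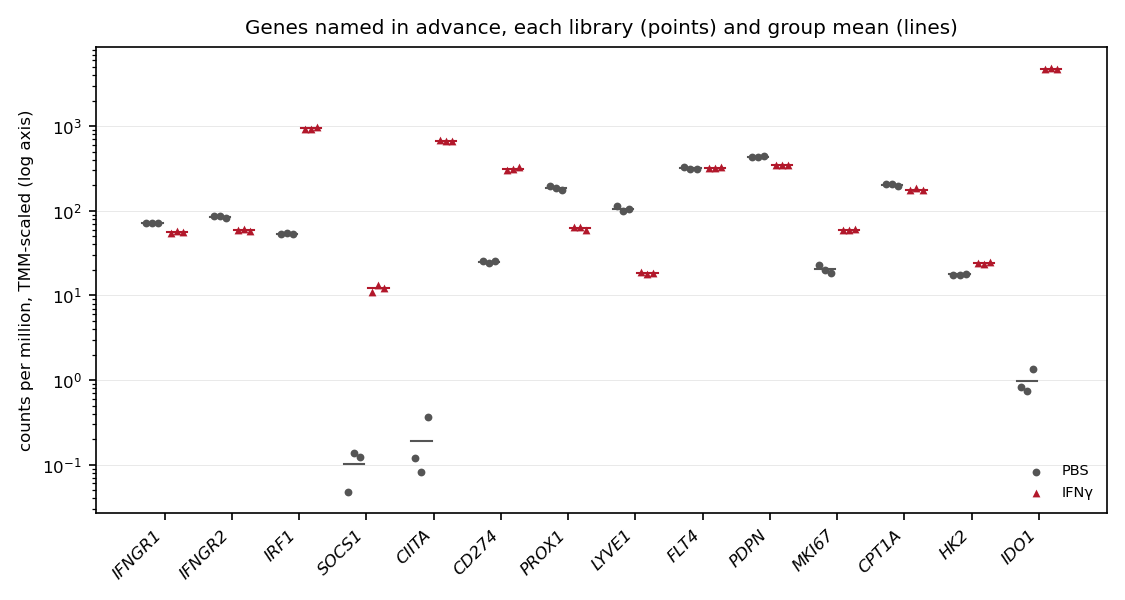
CPM of each library on a log axis for genes fixed before the data were examined, with PBS libraries as grey circles, IFNγ libraries as red triangles and lines at the mean of 3 libraries. IDO1, CIITA and SOCS1 lie near or under 1 CPM with PBS and at 4777, 674 and 12.2 CPM with IFNγ, PROX1 and LYVE1 lie lower with IFNγ, and the FLT4 values of the groups overlap.

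Of 20 pan-endothelial genes, 10 fell and 8 rose (camera adjusted p = 0.637), among them PECAM1, the adhesion molecule CD31 (-0.95 ± 0.037), EMCN (-0.81 ± 0.034) and NOS3, the endothelial nitric oxide synthase (-0.74 ± 0.043). Blood endothelial genes fell in 12 of 15 cases (camera adjusted p = 0.0033, and adjusted p = 0.28 with an estimated correlation). CXCR4, the receptor of the chemokine CXCL12, fell from 145 ± 4.06 to 18.7 ± 1.45 CPM, whereas the water channel AQP1 rose from 0.301 ± 0.0530 to 17.2 ± 0.947 CPM, with PLVAP and NRP1 as the other members that rose. Of 22 tip-cell and sprouting genes, 14 fell and 7 rose (camera adjusted p = 0.0127, and adjusted p = 0.183 with an estimated correlation). Beside CXCR4, NID2 changed by -2.82 ± 0.061 and the netrin receptor UNC5B by -2.28 ± 0.078.

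In the Notch pathway, 12 of 15 genes fell, DLL1 and HES4 rose and NOTCH2 did not pass the test (camera adjusted p = 0.000473, and adjusted p = 0.141 with an estimated correlation). The receptor NOTCH4 fell from 56.6 ± 1.84 to 17.0 ± 1.10 CPM and the Notch target HEY1 changed by -2.06 ± 0.061. Of 17 endothelial junction genes, 13 fell and 3 rose, ESAM and PKP4 among them (camera adjusted p = 0.00404, and adjusted p = 0.183 with an estimated correlation), with OCLN, which encodes the tight junction protein occludin, at -1.56 ± 0.14 and JAM3 at -1.09 ± 0.048. Basement membrane and extracellular matrix genes fell in 20 of 23 cases, and COL8A1 alone rose (camera adjusted p = 1.18e-05, and adjusted p = 0.28 with an estimated correlation). The collagenase gene MMP1 fell from 8.35 ± 0.696 to 0.231 ± 0.0834 CPM, beside MMP10 and MMP2. Of 18 endothelial-to-mesenchymal transition genes, 7 rose and 8 fell (camera adjusted p = 0.712). The actin-binding gene TAGLN rose from 8.91 ± 0.730 to 205 ± 27.0 CPM, while TGFBI (-1.89 ± 0.041) and the cadherin gene CDH2 (-1.79 ± 0.091) fell.

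In the list of G1/S and DNA replication, 30 of 31 genes rose and CCNE1 did not pass the test (camera adjusted p = 3.13e-10, and adjusted p = 0.101 with an estimated correlation). E2F1, a transcription factor of S-phase entry, rose from 2.73 ± 0.266 to 10.9 ± 0.423 CPM, E2F2 rose by 2.26 ± 0.18 and the replication factor CDC45 by 1.96 ± 0.085. All 33 tested G2/M and mitosis genes rose (camera adjusted p = 4.14e-12, and adjusted p = 0.101 with an estimated correlation). The proliferation marker MKI67 rose from 20.4 ± 2.43 to 59.9 ± 0.939 CPM (1.54 ± 0.056, edgeR adjusted p = 3.04e-16), the kinetochore gene NDC80 by 1.71 ± 0.075 and the mitotic transcription factor FOXM1 by 1.53 ± 0.046. Of 17 cell-cycle inhibitors, 10 fell and 5 rose (camera adjusted p = 0.128). CDKN1C (-1.86 ± 0.049) and CDKN2B (-1.65 ± 0.059) fell, and CDKN2C rose by 1.66 ± 0.11.

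Of 34 amino acid response genes and targets of the transcription factor ATF4, 31 rose, and ATF5, GDF15 and ALDH18A1 fell (camera adjusted p = 2.77e-10, and adjusted p = 0.339 with an estimated correlation). The serine synthesis enzymes PSAT1 and PHGDH rose from 16.3 ± 0.857 to 319 ± 30.1 CPM and from 1.84 ± 0.255 to 33.7 ± 5.35 CPM, and the glycine transporter SLC6A9 rose by 5.47 ± 0.20. In the list of tryptophan catabolism and NAD synthesis, 9 of 16 genes rose and 6 fell (camera adjusted p = 0.155). Beside IDO1, CD38, an enzyme that consumes NAD, rose by 3.45 ± 0.035, and WARS1, the tryptophanyl-tRNA synthetase, rose from 1111 ± 7.56 to 8989 ± 186 CPM. Nucleotide synthesis and one-carbon genes rose in 16 of 27 cases, and IMPDH1, NME1, PAICS and IMPDH2 fell, with 8 lower under library totals alone (camera adjusted p = 0.00404, and adjusted p = 0.331 with an estimated correlation). MTHFD2, a mitochondrial folate enzyme, rose by 3.04 ± 0.042. The other large rises there were of SAMHD1 (3.84 ± 0.038), which breaks down deoxynucleotides, and TYMP (3.74 ± 0.049), which breaks down thymidine, so these members act in degradation and not in synthesis. Of 25 genes of glutamine, arginine and polyamine metabolism, 12 rose and 7 fell (camera adjusted p = 0.432), and with library totals alone 8 were higher and 9 lower and their median of 0.040 became -0.062. GCH1, which starts the synthesis of tetrahydrobiopterin, rose by 3.56 ± 0.048, and the transaminase genes GPT2 and GOT1 rose by 1.77 ± 0.061 and 1.16 ± 0.049.

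**Figure D3:**
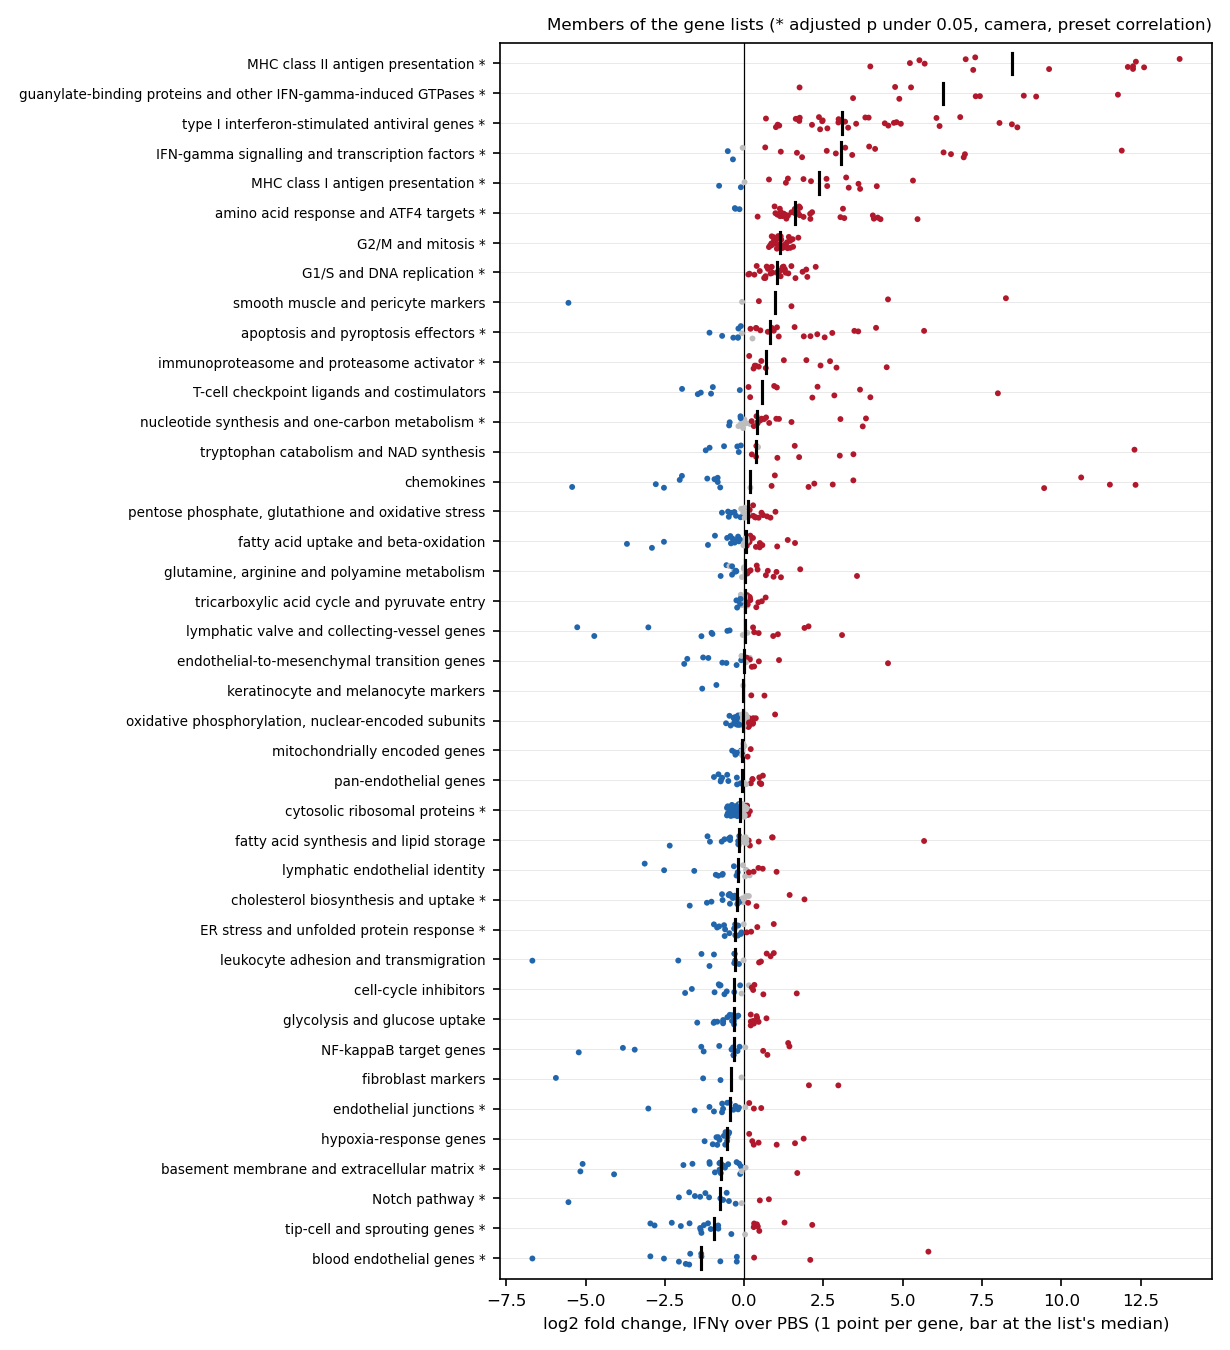
Log2 fold changes (IFNγ over PBS, fitted by edgeR) of the tested members of 41 gene lists, ordered by the list's median (black bar); red and blue genes passed an adjusted p of 0.05 and grey genes did not, and an asterisk marks the 19 lists past camera's adjusted p of 0.05 with the preset correlation. MHC class II genes lie farthest to the right, mitosis genes all lie above 0, and the fitted values of genes with 0 or 1 count in the PBS libraries, such as DES and HLA-DQA1, depend on the prior count.

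Of 25 glycolysis and glucose uptake genes, 16 fell and 9 rose (camera adjusted p = 0.108). PFKFB3, an activator of glycolysis, fell from 128 ± 2.09 to 66.7 ± 1.34 CPM, ALDOC changed by -1.48 ± 0.062 and PFKFB4 by -0.96 ± 0.13, whereas the hexokinase gene HK2 rose by 0.46 ± 0.045 (edgeR adjusted p = 9.13e-09). In the tricarboxylic acid cycle list, 13 of 31 genes rose and 7 fell (camera adjusted p = 0.432), but with library totals alone 5 were higher and 13 lower, and the median of 0.030 became -0.072. ME2 rose by 0.68 ± 0.041, FH by 0.56 ± 0.036 and MPC2 by 0.45 ± 0.042. Of 73 nuclear-encoded subunits of oxidative phosphorylation, 15 rose and 26 fell (camera adjusted p = 0.308), and with library totals alone 4 were higher and 46 lower. The complex I subunit gene NDUFA9 rose by 0.98 ± 0.055 while NDUFS5 changed by -0.57 ± 0.039. Of 13 mitochondrially encoded genes, 2 rose and 5 fell (camera adjusted p = 0.334), with 0 higher and 9 lower under library totals alone. Without PBS replicate 2, 1 of them was higher, and without IFNγ replicate 1, 1 was higher and 8 lower. MT-CO2 changed by -0.38 ± 0.046, and mitochondrial genes took 2.26 to 2.34% of the counts in PBS and 1.88 to 2.11% in IFNγ libraries.

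Of 36 genes of fatty acid uptake and beta-oxidation, 16 rose and 14 fell (camera adjusted p = 0.934). With library totals alone 9 were higher and 17 lower and their median of 0.059 became -0.044, and their mean was -0.18. The fatty acid binding proteins FABP4 and FABP5 fell from 1378 ± 34.9 to 106 ± 16.9 CPM and from 267.5 ± 11.8 to 46.4 ± 5.53 CPM. CPT1A, which admits fatty acids to mitochondria, fell by 0.19 ± 0.035 (edgeR adjusted p = 5.12e-05), and ACSL5, an acyl-CoA synthetase, rose by 1.60 ± 0.034. Of 25 fatty acid synthesis and lipid storage genes, 11 fell and 6 rose (camera adjusted p = 0.41). The median was -0.15 and the mean 0.011, and the list holds APOL1; FADS2, a fatty acid desaturase, changed by -1.16 ± 0.041. Cholesterol biosynthesis and uptake genes fell in 17 of 27 cases (camera adjusted p = 0.0204, and adjusted p = 0.328 with an estimated correlation), while CH25H, STARD4, INSIG1 and MYLIP rose. CH25H, which makes 25-hydroxycholesterol, rose by 1.90 ± 0.082, and the cholesterol exporter ABCA1 changed by -1.72 ± 0.091.

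Among stress lists, 15 of 20 genes of endoplasmic reticulum stress and the unfolded protein response fell (camera adjusted p = 0.0129, and adjusted p = 0.341 with an estimated correlation). The chaperone HSP90B1 fell from 1334 ± 17.0 to 739 ± 36.1 CPM and MANF changed by -0.95 ± 0.040, whereas the stress sensor ERN1 rose by 0.93 ± 0.042, as did XBP1, DNAJB9 and HERPUD1. Of 20 hypoxia-response genes, 13 fell and 7 rose (camera adjusted p = 0.108), with EGLN3 at 1.88 ± 0.056 and DDIT4 at 1.60 ± 0.049 against P4HA1 at -1.25 ± 0.039. In the list of pentose phosphate, glutathione and oxidative stress genes, 14 of 30 rose and 7 fell (camera adjusted p = 0.252), and with library totals alone 10 were higher and 11 lower. The cystine transporter SLC7A11 rose by 0.99 ± 0.038 and GCLM, of glutathione synthesis, by 0.83 ± 0.038. Cytosolic ribosomal protein genes fell in 41 of 71 cases and rose in 4 (camera adjusted p = 0.000808, and adjusted p = 0.647 with an estimated correlation), led by RPL23 (-0.54 ± 0.041). With library totals alone 0 rose and 59 fell, and 2 rose without PBS replicate 1, PBS replicate 2 or IFNγ replicate 1. They took 4.36 to 4.58% of the counts in PBS and 3.55 to 3.73% in IFNγ libraries.

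Markers of other skin cells were measured beside these lists. Smooth muscle and pericyte markers were higher in 4 of 6 cases (camera adjusted p = 0.155), with TAGLN, RGS5 (1.49 ± 0.081), ACTA2 and DES higher, while NOTCH3 fell from 3.41 ± 0.199 to 0.0712 ± 0.0408 CPM. DES had 0 counts in the PBS libraries and 0.578 CPM with IFNγ. A second member fell with library totals alone or without IFNγ replicate 3, giving 2 lower. Of 6 fibroblast markers, 2 rose and 3 fell (camera adjusted p = 0.57), with PDGFRA at 2.14 ± 0.131 CPM and COL1A2 at 2.32 ± 0.0883 CPM in the IFNγ libraries. Of 5 keratinocyte and melanocyte markers, 2 rose and 2 fell (camera adjusted p = 0.6), with DSP, which encodes desmoplakin, at -1.32 ± 0.049 and MITF at 0.23 ± 0.086. Without PBS replicate 2, PBS replicate 3, IFNγ replicate 2 or IFNγ replicate 3, 1 member of that list rose. MITF did not pass without PBS replicate 3 (0.14), IFNγ replicate 2 (0.17) or IFNγ replicate 3 (0.22), nor with library totals alone (0.12). Of 4 tested leukocyte markers, 2 fell, KIT from 2.75 ± 0.229 to 0.0608 ± 0.0420 CPM and ITGAM, and 1 rose without PBS replicate 2 or IFNγ replicate 2. Of 4 tested non-polyadenylated and nuclear RNAs, H1-2 (-0.82 ± 0.12) and H2BC5 (-0.33 ± 0.076) fell. The last 2 lists were too short for camera.

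Over the 41 lists tested, 19 passed camera with its preset correlation, 11 upward and 8 downward. With an estimated correlation camera passed 0 lists, 9 having an unadjusted p under 0.05, while fry, which does not compare a list with other genes, passed 38. Adjusted over the list alone, the counts of 38 of the 43 lists were the same, and in the other lists they became 11 higher chemokines, 11 lower cell-cycle inhibitors, 25 lower oxidative phosphorylation genes, 18 higher fatty acid uptake and oxidation genes and 17 higher nucleotide and one-carbon genes. Reads may be shared among close relatives such as the HLA, GBP, IFITM and APOL genes, so their values are less certain.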

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

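All the alternatives here were planned. Testing against a fold of 1.5 with glmTreat gave 2739 changed genes, 1394 higher and 1345 lower, which follows from its stricter null hypothesis. Gene lists passing numbered 0 with camera's estimated correlation, where 9 had an unadjusted p under 0.05, and 38 with fry, which does not set a list against other genes. With the replicate number as a block, 9576 genes changed, 4848 higher and 4728 lower, and 19 lists passed. Deviations of libraries that share a number correlated at -0.022, 0.039 and -0.029. PBS replicate 1 correlated best with IFNγ replicate 3 (0.052), and PBS replicate 2 with IFNγ replicate 2. All such correlations were weak, from -0.031 to 0.052, so they neither show nor exclude a pairing by number. Leaving out each library gave 8967 to 9390 changed genes. DESeq2 gave 9092 and limma-voom 9511 changed genes. Of all 19930 genes, DESeq2 gave no adjusted p for 4289, among them the 3335 with 0 counts in all 6 libraries. These 4289 held 0 of the reported calls. Among calls shared with the reported ones, 0 changed sign under any of these alternatives, though calls past the threshold in both fits can hardly do so. Of the 9523 reported calls, 1155 were lost with library totals alone and 663 in DESeq2. Leaving out a library lost 436 to 679 of them. Of 131 named genes, 129 kept their direction and side of the threshold under the 13 alternatives to the fit, its scaling, filter and libraries, wherever these gave a value. Most named genes were picked for large changes, so this says little about the other calls. FLT4, not past the threshold at 0.030, changed sign with library totals alone, to -0.073, by the shift of all genes, and stayed short of the threshold (edgeR adjusted p = 0.0609, and 0.0609 to 0.842 over the 13). With glmTreat 19 named genes lost their call, and at an adjusted p of 0.01 MITF alone did. MITF, at 0.23, kept its direction but not its call with library totals alone (0.12), in DESeq2 (0.23), and without PBS replicate 3 (0.14), IFNγ replicate 2 (0.17) or IFNγ replicate 3 (0.22). Its adjusted p was 0.2 in the first of these and ranged from 0.0078 to 0.2 over the same edgeR, DESeq2 and limma-voom alternatives, while the filter of 10 CPM in 3 libraries left it out. Of 86 counts of higher or lower list members, 65 stayed within 1.5 times under those 13 alternatives, and glmTreat moved 52 by more; in the 13, most of the larger moves came from library totals alone, the filter of 10 CPM or leaving out a library. At these depths, spreads and library numbers, 58% of simulated 1.2-fold changes were recovered, and which of the 3 limits this was not tested.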

Other observations

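The 6 gene lists described here were chosen after the main results were seen, as were the tests of endoplasmic reticulum stress and of IDO1 and the use of Fisher's exact test in weighing YAP and TAZ targets. Fisher's exact test was computed in both directions for each list, and only the p of the side in excess is given. A p that allowed for either direction would be larger. The test also treats genes as independent, which they are not.

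Complement genes rose with IFNγ: of 22 tested, 17 rose, CD55 fell and CFD, CD46, CLU and MASP1 did not pass edgeR's test. C1R and C1S, the proteases that start the classical pathway, rose from 1.33 ± 0.104 to 253.6 ± 13.3 CPM and from 0.641 ± 0.201 to 188 ± 5.85 CPM (mean ± SD, n = 3). SERPING1, the inhibitor of both, rose from 0.0955 ± 0.101 to 223.5 ± 2.85 CPM. C2 rose by 8.63 ± 0.37 on the log2 scale and CFB by 5.75 ± 0.26, from 0.370 ± 0.288 CPM with PBS. C4A and C4B are near-identical copies that may share reads. Raised genes were enriched in the list (one-sided Fisher's exact test p = 9.7e-05), and camera gave an adjusted p of 4.68e-05 over the 6 lists, or an adjusted p = 0.0537 with an estimated correlation. Since the list was chosen with the main results known, these p-values describe the rise and are no independent support for it.

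In a list of ligands, receptors, antagonists and targets of the BMP, activin and TGF-beta pathways, 16 of 28 genes were lower and 10 higher. Lowered genes were in excess by a one-sided Fisher's exact test (p = 0.0142), while camera gave an adjusted p of 0.114 over the 6 lists. Both activin subunits fell, INHBA from 125 ± 3.08 to 24.7 ± 2.74 CPM and INHBB as given above, while follistatin (FST), which binds activins, rose from 98.2 ± 2.33 to 242 ± 9.68 CPM. BMP2 changed by -1.40 ± 0.050 and the BMP regulator BMPER by -2.60 ± 0.086, but BMP4 rose by 0.80 ± 0.037. Of the early target genes, ID2 changed by -1.64 ± 0.053 and ID3 by -0.39 ± 0.042, and ID1 did not pass the test (-0.077 ± 0.056).

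The joint rise of replication and mitosis genes was set against 3 explanations. The choice among the scalings used here does not account for the rise. The median log2 fold change of both lists was 1.09, and 0.99 in the lower of the other 2 scalings. Library totals alone shifted all genes by a median of -0.10, so no other outcome was in reach and the test decides little. A change in total RNA per cell, which none of these scalings can show, was not tested. Less crowded cultures acting through YAP and TAZ stay open: 22 targets of these had a median of 0.147 (95% bootstrap interval -0.253 to 0.26), under the 0.3 set before the test, but 13 rose and 7 fell, so that a median decides little, and raised genes were in excess (one-sided Fisher's exact test p = 0.0233), while camera gave an adjusted p of 0.402, or an adjusted p = 0.55 with an estimated correlation. Lower p53 activity stays open. The test used 20 p53 targets that were in none of the earlier lists, so targets within those lists were not weighed. These 20 had a median of -0.267, and the interval of -0.473 to -0.01 includes the -0.3 set before the test. Of them, 13 were lower and 2 higher (one-sided Fisher's exact test for lowered genes p = 0.00627, camera adjusted p = 0.0188, and adjusted p = 0.141 with an estimated correlation). A response to IFNγ itself may account for the rise as well and was not told apart from these.

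The rise of ATF4 targets was set against 3 explanations too. For stress of the endoplasmic reticulum, the median of that list was -0.281 (95% bootstrap interval -0.533 to -0.094), so its genes did not rise as a set. The fall of 15 of its 20 genes was known when the test was set, so the test adds nothing to it. ERN1, XBP1, DNAJB9 and HERPUD1 rose, and a stress that leaves most of the list unraised stays open. Growth of the whole translation machinery, with all synthetases rising alike, is argued against. The 8 cytosolic tRNA synthetases not known as ATF4 targets had a median of 0.064 (-0.063 to 0.514), against 1.23 for 11 known targets, without WARS1. An exact two-sided permutation test over genes, which are not independent, gave p = 0.000741. Among the targets, AARS1, CARS1, GARS1 and SARS1 were in the list to be explained, so part of that contrast was known before. The groups also overlapped. KARS1 was at 0.80 and FARSB at 0.51 among the others, and TARS1 at 0.40, LARS1 at 0.50 and NARS1 at 0.67 among the targets. A shortage of tryptophan through induced IDO1 may account for the rise, as IDO1 changed by 12.31, but IDO1 would be higher with IFNγ under any activator of ATF4. That explanation cannot be told apart from others here, since amino acid levels were not measured in these data.

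The 6 libraries can be split into equal parts in 10 ways, too few for a share under 0.05. The real split gave 9523 changed genes and the highest of the other 9 gave 0 with edgeR, where 17 to 102 genes had an unadjusted p under 0.05, so 1 split of 10 gave as many. For gene lists passing camera with its preset correlation, the real split gave 19 and the highest other 17, with 12 or more in each of the other splits, and again 1 split of 10 gave as many. Each other split sets 2 libraries of a group with 1 of the other group, so part of the difference between the groups remains in it.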
